A study of Mus musculus with 8 samples.

How the data were processed

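RNA from the posterior tail bud of 8 mouse embryos was sequenced after Smart-seq2 library preparation, per the labels' protocols. Per the labels, the libraries formed 2 groups of 4, one labelled wild-type and the other labelled Epop knockout. Per the name of the deposited table, its values were RPKM (read counts scaled for gene length and library size) made by the authors. The submitters' processing notes name TopHat, DESeq2 and the mouse build mm10, without versions and without saying what each was used for. The gene annotation, the read counter and any filter are not given in the sources used here.

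The table held 26171 distinct gene symbols and 8 columns of per-library values. It had no header line, and 0 of the 8 value columns had a name. The name of the table listed 8 labels, 4 wild-type and 4 knockout, and all 8 were found among the sample titles. These labels are a possible key to the columns, but using them relies on the columns standing in the same order, which nothing inside the table states. The columns were inspected to establish their unit, and values of single genes were seen then, including Epop and the sex-linked marker Xist. The sex of the embryos was not analysed. Assignment by column order or by values was ruled out. The only use made of the values is the statement below that none was near 0 for Epop. All 8 columns were left out of every test, which was a choice of procedure. The planned limma test of knockout against wild-type, the gene list tests and the alternative settings listed for them were therefore not run. The sample titles carry numbers, and 1 number, 11, occurs in both groups. The titles do not say what the numbers count.

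The symbol column was read with Python 3.11.15. Of the 26171 symbols, 24889 matched a symbol in the reference table of gene names. Before the data were examined, 39 gene lists with 473 distinct genes had been fixed, and 461 of these genes had a line in the table. The 12 genes without a line were the members of the list of mitochondrially encoded genes. Gene positions were taken from the GENCODE M21 annotation, which uses the same build as the submitters' notes name, and are counted from 1.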

Results

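The series measured polyadenylated RNA by sequencing in the tail end of mouse embryos at embryonic day 8.5, matched at 4 to 5 somites. Of its 8 libraries, 4 were labelled wild-type and 4 were labelled knockout for Epop. Epop encodes an accessory protein of Polycomb repressive complex 2 (PRC2), which places a repressive methyl mark on histone H3. The series title poses the question of whether Epop is needed for the regulation of Hox genes, the homeobox genes that set position along the body axis. The comparison implied by the design is therefore between the 4 libraries labelled knockout and the 4 labelled wild-type, with Epop and the Hox genes as the genes of first interest.

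No expression value or difference between the genotypes is reported for this comparison. The deposited expression table gave a gene symbol and 8 value columns per line and had no header line. None of the 8 value columns carried a name. The name of the table listed 8 labels, 4 wild-type and 4 knockout, whose numbers matched those of the sample titles. It did not state that the columns followed the order of these labels. Reading the labels as the column order would have assigned each column by its position, and by choice this was not done. Columns were not assigned by their values either. The sequencing depth of each library was not analysed here.

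The genes that the question concerns were listed in the table. A listing does not show that a gene was expressed. Epop had 1 line. When the table was inspected to establish its unit, none of the 8 columns held a value near 0 for Epop. No cutoff for this had been fixed beforehand. Whichever columns belong to the libraries labelled knockout, their values for Epop were therefore not near 0. The reads behind these values were not examined, so intact Epop RNA cannot be told from a remaining part of it. Whether Epop RNA was lower in the knockout libraries than in the wild-type libraries was not tested. The labels do not describe the allele, so whether it would remove the RNA is not known here. In the GENCODE M21 annotation of the mm10 build, Epop (ENSMUSG00000043439.5) is a protein-coding gene on the minus strand of chromosome 11, from position 97627389 to 97629702, with 1 annotated transcript of 1 exon. All 39 Hox genes had a line. The 11 Hoxa genes lie on chromosome 6 between positions 52155590 and 52260880. The 10 Hoxb genes lie on chromosome 11, as Epop does, between positions 96194316 and 96368256. The 9 Hoxc genes lie on chromosome 15 between positions 102921103 and 103036852, and the 9 Hoxd genes lie on chromosome 2 between positions 74668310 and 74765142. By paralog group, 12 of the Hox genes belong to groups 1 to 4, 15 to groups 5 to 9 and 12 to groups 10 to 13.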

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

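None of the settings chosen before the data were examined was run, because no comparison between the genotypes was made. That was a choice not to read the labels in the table's name as the order of its unnamed columns. No paired analysis was possible from the labels, whichever way the columns are assigned. The 2 groups share only 1 number, 11, and the labels do not say that it marks a pair. After seeing the data, the match of gene symbols was repeated with RefSeq synonyms added, which raised the matched symbols from 24889 to 26133 of 26171. Without the older symbols kept as aliases, 461 of the 473 list genes had a line, as with them.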
